A study of Homo sapiens with 18 samples.

How the data were processed

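Poly(A) RNA from 18 libraries was sequenced on an Illumina HiSeq3000 instrument, 3 libraries for each of 6 groups, per the labels. The groups are MCF7L and T47D cells, each as parental, TamR and TamR with sapitinib. Groups were taken from the labels as given, and every column of the count table was mapped to its library by name.

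The authors deposited a table of raw read counts per gene and library, and the submitters' processing notes name hg19, TopHat2, SAMtools, Picard and DESeq2 without roles or versions. The read counter and the annotation behind the deposited counts are not given in the sources used here. The authors also deposited a table for each comparison of TamR with parental cells and of sapitinib with TamR cells in a line, with log2 fold changes and their standard errors from DESeq2 per the file headers. These deposited tables hold adjusted p-values from DESeq2, per the file headers, for the genes past the authors' thresholds only. They were used only to compare direction and calls, and all values of the report were computed from the deposited counts.

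The count table holds 23459 gene IDs, of which 23308 matched a symbol in a GRCh38.p14 gene table and 151 did not, with 0.8653% of all counts. IDs without a count in any library numbered 2192. The gene table was used for names and for the order of neighbours along chromosomes. Library totals ran from 10447329 to 12807241 counts (median 11538680). Replicates of a group differed by more than counting noise in every pair, with a chi-square per degree of freedom from 2.385 to 36.2. Mitochondrially encoded genes are not in the table.

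Genes were tested with edgeR 4.0.16 in R 4.3.3, in 1 fit of the 9 libraries of each line. TMM factors scaled the libraries, filterByExpr removed genes with low counts (minimum count 10, minimum total 15), and quasi-likelihood F tests gave p-values that were adjusted by the Benjamini-Hochberg method. A gene was called at an adjusted p under 0.05. The difference between lines was tested as an interaction in 1 fit of all 18 libraries, once for TamR against parental and once for sapitinib against TamR. CPM values use the TMM factors of the fit of the line, and log2 CPM for components and windows a prior count of 2. Values are mean ± SD with n = 3 libraries.

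The genes named were fixed by a rule written before the files were opened. In each comparison within a line it takes the 8 largest increases and the 8 largest decreases among called genes whose 2 groups do not overlap in CPM, with a mean of at least 10 CPM in the higher group and without uncharacterised symbols. In each interaction it takes the 4 most positive and the 4 most negative differences by the same filters without the overlap condition. In every comparison it takes EGFR, ERBB2, ERBB3, ERBB4, ESR1, PGR, GREB1 and TFF1. Of each gene list described it takes up to 3 called members with the largest change, and of genes changed alike in both lines 4 per direction. For a gene with no count in a group the fold is given as a lower bound against a floor of 3 counts over the group, and for 1 to 3 counts as a ratio with a 95% counting interval.

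Gene lists were written before the files were opened: ERBB receptors and ligands, ERK pathway output, FOXO-responsive, estrogen-response, mitotic, DNA replication, cholesterol, fatty acid synthesis, interferon-stimulated, MHC class I, ATF4 response, chaperone, hypoxia, p53 target, mesenchymal, luminal, basal, fibroblast with immune and endothelial markers, lysosome, NRF2 target, aryl hydrocarbon receptor target, other receptor tyrosine kinase, ribosomal protein and mitochondrially encoded genes, 24 in all. Lists with at least 3 tested members were tested by camera in limma 3.58.1 with the preset correlation of 0.01, and again with the correlation estimated from the data, each adjusted over the 23 lists tested. Members called are counted with the adjustment over all genes and with the adjustment over the list alone.

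Genes called in both lines were counted per direction beside the overlap of independent lists. Genes called in both contrasts of a line were counted beside independent calls and beside 20 simulations of unchanged groups, since both contrasts use the TamR libraries. Regional expression was compared in windows of 25 neighbouring autosomal genes with a mean log2 CPM of at least 3. This window test was added after the distances between groups were seen.

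The test was tried on simulated data with 200 genes changed by 1.5, 2 or 4 times. In MCF7L TamR against parental (14689 genes) 29.9%, 76.1% and 95.5% of them were recovered, and in T47D (15300 genes) 49.3%, 76.1% and 97%. For sapitinib in MCF7L (14681 genes) the shares were 31.3%, 68.7% and 97%, and in T47D (15278 genes) 62.7%, 74.6% and 93.9%. For the differences between lines (15811 genes) they were 14.9%, 56.7% and 83.3% for TamR and 22.4%, 62.7% and 69.7% for sapitinib. False calls made up 2.83% to 5.76% of the calls.

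Alternatives fixed in advance were DESeq2 1.42.0 in place of edgeR, RLE size factors or library sizes alone in place of TMM, no filter on low counts, other sets of libraries in the fit (6, 12 or all 18), the replicate number as a block, each library left out in turn, camera with an estimated correlation, and a log2 fold change of at least 1 in both contrasts. Leaving out libraries for overlaps, opposite changes, single gene lists and numbers of lists was added later. The libraries of the compared groups were also split in every way within a line (10 splits) and in 100 ways for the differences between lines.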

Results

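Gene expression was measured by poly(A) RNA sequencing in derivatives of 2 estrogen receptor positive breast cancer cell lines, MCF7L and T47D. Each line contributed 3 groups of 3 libraries, 18 libraries in all: the parental cells, a derivative resistant to tamoxifen (TamR), and TamR cells given sapitinib, a kinase inhibitor of EGFR, HER2 and ERBB3 also known as AZD8931. The labels state separate biological replicates. Parental cells were kept in RPMI medium with fetal bovine serum, whereas TamR cells were kept without phenol red, in charcoal-stripped serum, with 100 nM tamoxifen. A difference between TamR and parental cells therefore holds the medium and the drug as well as the derivative. The dose and the duration of sapitinib for these libraries are not given in the sources used here. Library totals ran from 10447329 to 12807241 counts over genes, with a median of 11538680. CPM, counts scaled to library depth, is given below as mean ± SD of the 3 libraries of a group (n = 3).

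The libraries separated first by TamR line and then by treatment history. Component 1 held 59.9% of the variance of log2 CPM and set the T47D TamR libraries, with and without sapitinib, apart from all others. Component 2 held 20.5% and set both parental groups apart from the MCF7L TamR libraries. Component 3 held 8.28% and set the 2 parental groups apart, with MCF7L parental at 46.2 to 62.5 and the libraries labelled T47D parental at -57.4 to -52.3. It also set sapitinib apart from TamR alone. The values were -33.95 to -22.1 against 4.756 to 22.49 in MCF7L and -25.07 to -17.41 against 30.05 to 34.26 in T47D. The libraries labelled T47D parental lay nearer MCF7L parental (root mean square log2 difference 1.02 over 15961 genes) than T47D TamR (1.66). MCF7L parental likewise lay nearer those libraries than MCF7L TamR (1.33), so this distance alone does not set the libraries labelled T47D parental apart. Regional expression followed the same order. Expressed autosomal genes were put in 421 windows of 25 neighbours, and the median log2 difference of each window was taken, so that a gained or lost chromosome segment appears as a shifted window. Between the libraries labelled T47D parental and MCF7L parental 2 windows differed by more than 0.5, while between T47D TamR and the libraries labelled T47D parental 63 did. MCF7L TamR and parental differed so in 17 windows, the 2 TamR lines in 97. With sapitinib no more than 1 window differed so in either line. Around TBX2, in a segment known to be amplified in MCF-7 cells, the median of 21 neighbouring genes was 0.13 higher on the log2 scale in the libraries labelled T47D parental than in MCF7L parental. It was far lower in T47D TamR than in MCF7L TamR (-1.67). TBX2 itself, chosen after its values were seen, stood at 244 ± 5.63 CPM in MCF7L parental, 235 ± 12.4 in the libraries labelled T47D parental and 15.4 ± 2.56 in T47D TamR (n = 3). MTAP and TFAP2B, chosen likewise after their values were seen, stood between the other 2 groups in the libraries labelled T47D parental. MTAP was at 6.54 ± 0.0717 CPM in MCF7L parental, 13.6 ± 4.45 in those libraries and 60.3 ± 1.83 in T47D TamR, and TFAP2B at 0.427 ± 0.0402, 4.67 ± 1.74 and 178 ± 4.71. The regional profile of the libraries labelled T47D parental thus lies on the MCF7L side, and every comparison that uses them is given with that fact.

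**Figure D1:**
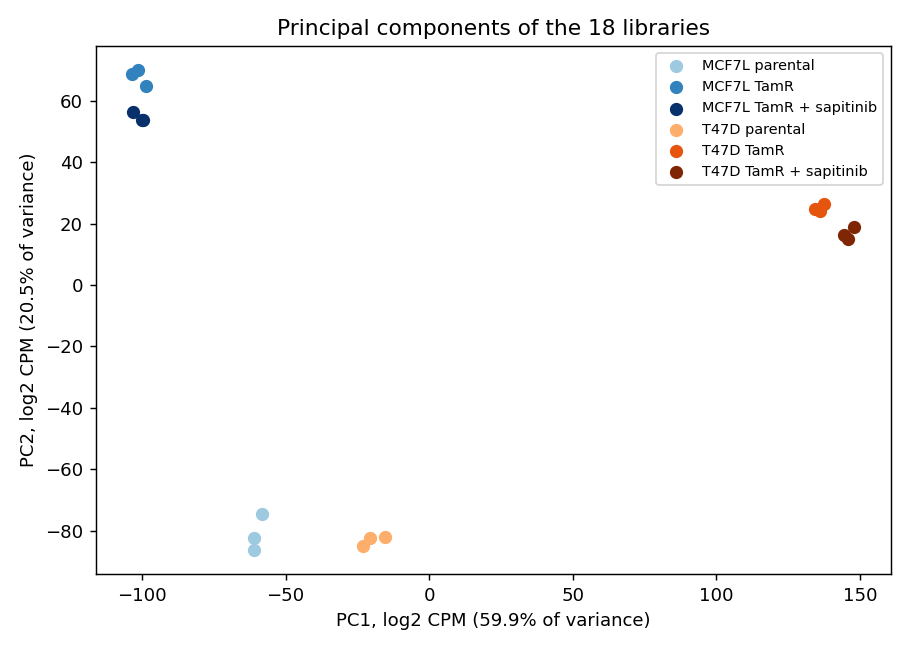
Principal components 1 and 2 of log2 CPM, one point per library, coloured by group. On these 2 components the libraries labelled T47D parental lie nearer MCF7L parental than T47D TamR, and the T47D TamR libraries, with and without sapitinib, lie apart at PC1 of 134 to 148.

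**Figure D2:**
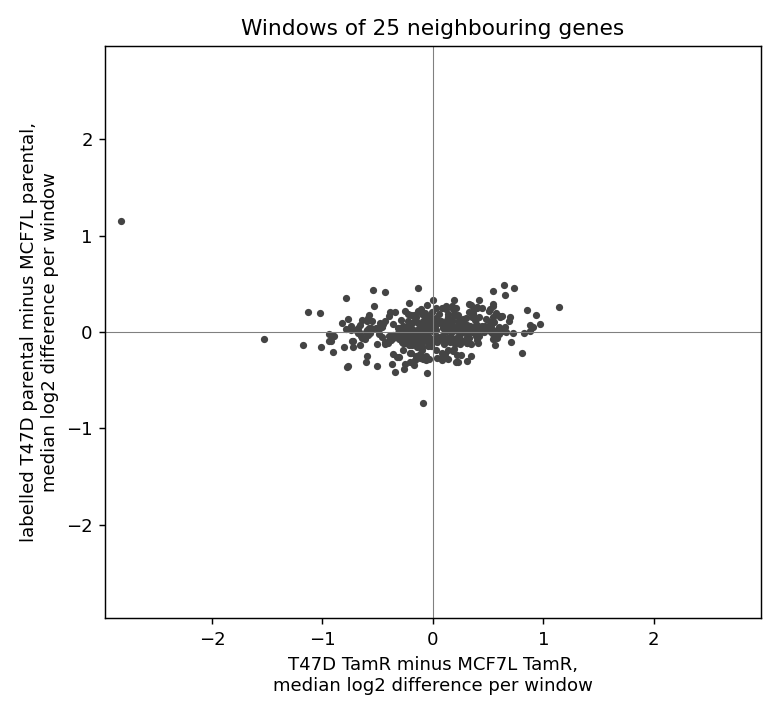
Median log2 expression difference of T47D minus MCF7L libraries in each of 421 windows of 25 neighbouring genes, for TamR libraries on the horizontal axis and for parental libraries, as labelled, on the vertical axis. The TamR differences spread far more widely than the parental ones, with 97 against 2 windows beyond 0.5, and 1 protocadherin window lies at -2.83 and 1.16.

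What separates tamoxifen-resistant MCF7L cells from parental cells was the first question. MCF7L TamR cells had lower levels of all tested interferon-stimulated genes and of most estrogen-response genes, and higher levels of EGFR, of its ligand genes AREG and BTC and of most ERK output genes. EGFR (gene ID 1956), the receptor that sapitinib inhibits, rose from 4.02 ± 1.54 to 82.8 ± 32 CPM (log2 fold change 4.37, SE 0.338, adjusted p = 2.68e-06, edgeR). Of its ligands, AREG rose from 449 ± 117 to 4304 ± 492 CPM (log2 fold change 3.26) and BTC from 2.74 ± 0.855 to 32.5 ± 1.51 (log2 fold change 3.57). GREB1 (gene ID 9687), an estrogen receptor target, fell from 417 ± 23.2 to 9.21 ± 5.58 CPM (log2 fold change -5.51, SE 0.367, adjusted p = 9.67e-07).

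All 31 tested interferon-stimulated genes were lower (31 adjusted over the list alone), with a median log2 fold change of -3.93 (camera adjusted p = 2.8e-25, and adjusted p = 0.417 with an estimated correlation). OAS3, a sensor of viral RNA, fell from 153 ± 52 to 1.43 ± 0.323 CPM, OAS2 from 42.5 ± 22.9 to 0.320 ± 0.0644, and XAF1 from 32.2 ± 13.1 to a trace (parental over TamR ratio 558, counting interval 154 to 4610). Of the MHC class I antigen presentation genes, 6 of 12 were lower (6 adjusted over the list alone) and none higher, among them the peptide transporters TAP1 (log2 fold change -3.23) and TAP2 (-1.39) and the peptide loader TAPBP (-3.11). The list gave camera adjusted p = 0.00106, and adjusted p = 0.651 with an estimated correlation. Estrogen-response genes gave 4 of 34 higher and 19 lower (4 and 21 adjusted over the list alone). Their median was -0.58 (camera adjusted p = 2.35e-08, and adjusted p = 0.417 with an estimated correlation). CXCL12 fell from 110.4 ± 47.6 to 0.111 ± 0.128 CPM, SUSD3 from 51.1 ± 5.94 to 0.146 ± 0.0557, CA12 from 226 ± 14.8 to 3.27 ± 1.91, and the progesterone receptor gene PGR from 262 ± 39.8 to 35.5 ± 17. ESR1, the estrogen receptor itself, changed little by comparison (log2 fold change -0.30, SE 0.0761, adjusted p = 0.00812), and TFF1 did not pass the test (log2 fold change 0.70, SE 0.369, adjusted p = 0.151).

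ERK pathway output genes went the other way, with 14 of 19 higher and 3 lower (14 and 3 adjusted over the list alone). Their median was 2.16 (camera adjusted p = 1.5e-05, and adjusted p = 0.605 with an estimated correlation). SPRY4, a feedback inhibitor of ERK signalling, rose from 1.85 ± 1.26 to 165 ± 37.7 CPM and the transcription factor gene ETV5 to 70.5 ± 9.85 (log2 fold change 5.60), whereas EPHA4 fell from 75.7 ± 13.3 to 1.54 ± 0.901. For ERBB receptors and ligands the counts were 5 of 12 higher and 2 lower (5 and 2 adjusted over the list alone). Their median was 0.26 (camera adjusted p = 0.0200, and adjusted p = 0.417 with an estimated correlation). The call of that list ended without MCF7L parental replicate 2 (adjusted p = 0.0586) or replicate 3 (adjusted p = 0.0883). ERBB4 fell from 8.58 ± 5.46 to 0.230 ± 0.171 CPM (log2 fold change -5.15, SE 0.688, adjusted p = 0.000127). ERBB2, which encodes HER2, did not pass the test (279 ± 31.8 CPM against 235 ± 29.7, adjusted p = 0.0882), though it did with all 18 libraries in the fit (adjusted p = 0.0112) and without MCF7L parental replicate 1 (adjusted p = 0.0415). ERBB3 stood at 317 ± 24.8 CPM against 289 ± 19.4 (adjusted p = 0.232). Luminal epithelial genes gave 3 of 20 higher and 9 lower (3 and 10 adjusted over the list alone). MUC1 fell from 1799 ± 857 to 51.5 ± 7.5 CPM, GATA3 from 266 ± 27 to 41.5 ± 7.15 and the keratin gene KRT18 from 3484 ± 792 to 802 ± 59.4. Mesenchymal genes gave 4 of 9 higher and 3 lower (4 and 3 adjusted over the list alone). The collagen crosslinker gene LOX rose from 1.64 ± 0.855 to 129.5 ± 37 CPM and VIM from 4.50 ± 0.082 to 23.6 ± 2.37. ATF4 and amino acid response genes gave 14 of 20 higher and 2 lower (14 and 2 adjusted over the list alone). SLC7A11 rose by 2.94 and CHAC1 by 3.15 on the log2 scale, while PSAT1, an enzyme of serine synthesis, fell from 25.7 ± 3.7 to 0.111 ± 0.128 CPM. None of these 3 lists passed camera (adjusted p = 0.113, 0.0926 and 0.139; 0.862, 0.417 and 0.862 with an estimated correlation). Each passed in some settings. The luminal list did so without MCF7L parental replicate 3 (adjusted p = 0.0118), the mesenchymal list without replicate 1 (adjusted p = 0.0375) and the ATF4 list without the filter on low counts (adjusted p = 0.0152). The 22 mitotic genes had a median of -0.02 and a range of -0.39 to 0.23, and 0 passed in edgeR, 0 at an unadjusted p under 0.05 and 0 in DESeq2.

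Several genes were on in one group and absent from the other. FUOM, RAMP1, ABCA4, ADRA2A, CHGA, PRAME, MAOB and VSTM2L had no count in the MCF7L TamR libraries and were at least 241-, 226-, 226-, 144-, 142-, 134-, 113- and 112-fold lower there, against a floor of 3 counts over the group. ZC3HAV1L, GALNT5 and PABPC1L2B had no count in parental cells and were at least 200-, 180- and 139-fold higher in TamR, and PABPC1L2B is uncertain because it has a near-identical copy. The transcription factor genes SOX11 and MEF2C reached 76.5 ± 7.26 and 64.1 ± 21.2 CPM from 0.112 ± 0.133 and 0.183 ± 0.188, and the growth factor gene BMP2 53.1 ± 23.2 from 0.141 ± 0.0413. EYA4 (TamR over parental ratio 1090, counting interval 195 to 43000) and ARHGAP20 (ratio 660, counting interval 118 to 26100) had 1 count in parental cells.

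In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 3162 genes were higher and 3369 lower in MCF7L TamR among 14753 tested (adjusted p under 0.05), of which 1349 and 1712 differed at least 2-fold. No alternative moved these counts past the margin set in advance for a changed count.

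The same comparison in T47D set TamR cells against the libraries labelled T47D parental, whose regional profile lies nearer MCF7L (63 windows beyond 0.5 from T47D TamR, 2 from MCF7L parental). Relative to those libraries, T47D TamR cells had higher levels of all tested mitotic and replication genes and lower levels of most estrogen-response genes. MKI67, a proliferation marker gene, was low in the reference itself, at 81.53 to 103.8 CPM scaled over all 18 libraries. It stood at 302.3 to 467.9 CPM in MCF7L parental, 302.7 to 383 in MCF7L TamR and 320.9 to 348.5 in T47D TamR. BUB1, a mitotic checkpoint kinase gene, stood at 78.9 ± 3.26 CPM against 11.7 ± 3.19 (log2 fold change 2.75, SE 0.229, adjusted p = 2.61e-06, edgeR) and MCM10, which loads the replication machinery, at 86.5 ± 3.28 CPM against 9.30 ± 2.77 (log2 fold change 3.22, SE 0.395, adjusted p = 5.42e-05). GREB1 stood at 0.974 ± 0.451 CPM against 188 ± 24.2 (log2 fold change -7.58, SE 0.246, adjusted p = 3.97e-09) and PGR at 0.733 ± 0.362 CPM against 158 ± 70 (log2 fold change -7.74, SE 0.452, adjusted p = 3.65e-07). ESR1 was also lower, at 36.1 ± 5.33 CPM against 233 ± 28.4 (log2 fold change -2.69, SE 0.112, adjusted p = 1.2e-08).

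All 22 mitotic genes (22 adjusted over the list alone) and all 25 DNA replication genes (25 adjusted over the list alone) were higher than in the libraries labelled T47D parental, with medians of 1.95 and 1.53. The mitotic list gave camera adjusted p = 0.000562, and adjusted p = 0.862 with an estimated correlation, and the replication list camera adjusted p = 3.99e-08, and adjusted p = 0.646 with an estimated correlation. Besides BUB1 and MCM10, BUB1B rose by 2.70, CENPA by 2.51, UHRF1 by 2.72 and POLE2 by 2.68 on the log2 scale. Estrogen-response genes gave 7 of 34 higher and 23 lower (7 and 23 adjusted over the list alone). Their median was -1.53 (camera adjusted p = 0.000394, and adjusted p = 0.646 with an estimated correlation). CXCL12 stood at 0.279 ± 0.243 CPM against 42.4 ± 21.1 and TFF1 at 3.57 ± 1.64 CPM against 36.4 ± 2.29 (log2 fold change -3.33, SE 0.274, adjusted p = 1.48e-06). FOXO-responsive genes, which PI3K and AKT signalling hold down, gave 1 of 19 higher and 14 lower (1 and 14 adjusted over the list alone). Their median was -0.85 (camera adjusted p = 0.000394, and adjusted p = 0.646 with an estimated correlation). SESN3 stood at 0.153 ± 0.0564 CPM against 71.1 ± 16.1, the insulin receptor substrate gene IRS2 at 0.461 ± 0.175 CPM against 43.8 ± 4.22 and IGF1R at 100.4 ± 18.7 CPM against 319 ± 5.48.

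MHC class I antigen presentation genes gave 12 of 13 higher and 0 lower (12 and 0 adjusted over the list alone). Their median was 0.96 (camera adjusted p = 0.0299, and adjusted p = 0.862 with an estimated correlation). The immunoproteasome subunit genes PSMB8 and PSMB9 were higher by 3.05 and 2.26 on the log2 scale, and HLA-B stood at 524 ± 87.1 CPM against 138 ± 63.3. ERK output genes gave 4 of 17 higher and 11 lower (4 and 11 adjusted over the list alone). Their median was -0.81 (camera adjusted p = 0.215, and adjusted p = 0.894 with an estimated correlation). Interferon-stimulated genes gave 22 of 32 higher and 4 lower (22 and 4 adjusted over the list alone). This list passed camera only without T47D parental replicate 1 (adjusted p = 0.00521) or without the filter on low counts (adjusted p = 0.0335), against 0.0872 here and 0.894 with an estimated correlation. IFI44 stood at 15.4 ± 1.9 CPM against 0.920 ± 0.121, OAS3 at 284 ± 15.3 CPM against 56.1 ± 17.8 and MX1 at 116 ± 2.77 CPM against 23.0 ± 17.9. ERBB receptors and ligands gave 6 of 13 higher and 4 lower (6 and 4 adjusted over the list alone). EGFR stood at 86.9 ± 15.4 CPM against 24.4 ± 10.2 (log2 fold change 1.83, SE 0.246, adjusted p = 9.96e-05), the ligands EPGN at 36.4 ± 11.5 CPM against 2.08 ± 0.995 and AREG at 81.2 ± 34.6 CPM against 17.6 ± 17.4, and ERBB4 at 0.305 ± 0.224 CPM against 24.8 ± 4.83. ERBB2 was slightly higher (log2 fold change 0.29, SE 0.0568, adjusted p = 0.00078) and ERBB3 did not pass (log2 fold change 0.05, SE 0.0632, adjusted p = 0.53). Mesenchymal genes gave 3 of 11 higher and 6 lower (3 and 6 adjusted over the list alone), with VIM at 0.121 ± 0.0497 CPM against 36.0 ± 2.66. Luminal genes gave 5 of 20 higher and 5 lower (5 and 5 adjusted over the list alone), with ELF3 at 1.28 and PRLR at -0.88 on the log2 scale. ATF4 response genes gave 12 of 21 higher and 3 lower (12 and 3 adjusted over the list alone). PSAT1 stood at 0.153 ± 0.0564 CPM against 15.2 ± 1.79 and ALDH1L2 up by 3.51. Camera passed none of the ERBB, mesenchymal, luminal and ATF4 lists (adjusted p = 0.916, 0.215, 0.716 and 0.147; 0.968, 0.862, 0.894 and 0.862 with an estimated correlation).

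FLG, DENND1B, STOX2, MME, GNG11 and PCED1B had no count in T47D TamR and were at least 1240-, 494-, 175-, 172-, 152- and 128-fold lower than in the libraries labelled T47D parental, against a floor of 3 counts over the group. AFF3 had 1 count in T47D TamR (labelled parental over TamR ratio 1250, counting interval 224 to 49500). TEX11, MDFI and TBX18 had no count in the libraries labelled T47D parental and were at least 358-, 245- and 164-fold higher in T47D TamR, and FSTL5 had 2 counts there (TamR over labelled parental ratio 1200, counting interval 331 to 9880). Among the largest increases CTAG1B stood at 223 ± 18.8 CPM against 0.118 ± 0.102, PAGE5 at 132 ± 22.9 CPM against 0.114 ± 0.0441, SSX5 at 40.3 ± 4.08 CPM and CSAG3 at 14.5 ± 2.1 in T47D TamR, and among the largest decreases SPANXA2 at 0.117 ± 0.102 CPM against 137 ± 60.6. These 5 belong to families of near-identical copies, and their single values are uncertain. In edgeR's test 5778 genes were higher and 5697 lower among 15372 tested (adjusted p under 0.05), 2112 and 2846 of them at least 2-fold.

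Whether the difference from the parental libraries was alike in the 2 lines was tested directly, as the T47D minus MCF7L difference of the 2 changes over all 18 libraries. It rests on the libraries labelled T47D parental, which differ from MCF7L parental in 2 of 421 windows and from T47D TamR in 63. Interferon-stimulated genes parted most, with 30 of 32 higher in the T47D change (30 adjusted over the list alone) and a median difference of 5.05 on the log2 scale (camera adjusted p = 1.65e-21, and adjusted p = 0.401 with an estimated correlation). Of the MHC class I genes 10 of 13 were higher (11 adjusted over the list alone), median 2.05 (camera adjusted p = 6.2e-07, and adjusted p = 0.587 with an estimated correlation). Mitotic genes (22 of 22 higher, 22 adjusted over the list alone) and replication genes (24 of 25, 24 adjusted over the list alone) followed, with medians of 1.98 (camera adjusted p = 0.000335, and adjusted p = 0.755 with an estimated correlation) and 1.39 (camera adjusted p = 2.0e-05, and adjusted p = 0.755 with an estimated correlation). The mitotic list differed by a median of 0.138 between the TamR lines, so its difference lay mostly between the parental groups as labelled. ERK output genes went the other way, with 16 of 19 lower and 3 higher (16 and 3 adjusted over the list alone), median -2.36 (camera adjusted p = 0.000335, and adjusted p = 0.738 with an estimated correlation).

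The rise of EGFR was smaller in T47D (difference -2.56, SE 0.443, adjusted p = 0.000108, edgeR), and ESR1, PGR and GREB1 fell further there, while TFF1 fell there and did not pass in MCF7L (differences -2.41, -4.88, -2.09 and -4.04, adjusted p = 1.29e-10, 3.4e-06, 0.00706 and 7.63e-06). ERBB2, ERBB3 and ERBB4 did not pass (adjusted p = 0.886, 0.378 and 0.393). The most negative differences were those of GALNT5 (adjusted p = 9.61e-05), SOX2, MAF and VWDE, and the most positive those of SSX5, MDFI, FAM133A and P2RX7 (adjusted p = 1.64e-11). Without MCF7L parental replicate 3 the call of MDFI ended (adjusted p = 1). In all, 4556 genes were higher and 4714 lower in the difference among 15961 tested (edgeR). Changes in the same direction were no rarity. Of 14256 genes tested in both lines, 1217 were higher in both, where independent lists would share 1072.2, and 1720 lower in both, against 1242.5. With a log2 fold change of at least 1 in both lines the counts were 288 and 732. Another 1947 went opposite ways, against 2308.9, and the fold changes correlated at r = 0.2 across genes, which are not independent replicates. LDHB, a lactate dehydrogenase subunit gene, rose from 0.968 ± 0.587 to 133 ± 2.9 CPM in MCF7L and stood at 64.7 ± 8.92 CPM against 0.793 ± 0.874 in T47D. WNT5A, TMTC1 and MEIS2 were higher in both (log2 fold changes 5.28, 5.59 and 7.55 in MCF7L, 5.52, 6.16 and 5.32 in T47D). TENM3 fell from 140.2 ± 18 to 0.338 ± 0.297 CPM in MCF7L and stood at 0.276 ± 0.267 CPM against 195 ± 31.5 in T47D, and FUOM, IL20 and ZIC4 fell in both, from 20.9 ± 3.51, 41.0 ± 1.87 and 13 ± 0.657 CPM in MCF7L and 20.8 ± 3.24, 13.7 ± 5.73 and 23.97 ± 3.81 in T47D to 2 counts or fewer in any TamR group.

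The effect of sapitinib was asked within the TamR cells. These comparisons do not use the parental libraries except for the shared filter on low counts, TMM scaling and estimate of the spread. In MCF7L TamR cells sapitinib lowered all tested mitotic genes, most ERK output genes and the EGFR ligand genes AREG, BTC and HBEGF. It raised a minority of FOXO-responsive genes, PIK3IP1 and TXNIP among them, and 2 of 5 aryl hydrocarbon receptor targets, CYP1A1 and CYP1B1. AREG (gene ID 374) fell from 4304 ± 492 to 245 ± 44 CPM (log2 fold change -4.13, SE 0.237, adjusted p = 1.09e-05, edgeR). CYP1A1 (gene ID 1543), a target of the aryl hydrocarbon receptor, rose from 0.619 ± 0.409 to 49.0 ± 18 CPM (log2 fold change 6.25, SE 0.667, adjusted p = 0.000303). The drug target genes themselves did not pass the edgeR test. EGFR stood at 58.7 ± 7.99 CPM against 82.8 ± 32 (adjusted p = 0.234). Without MCF7L TamR replicate 2 it was called (log2 fold change -0.734, adjusted p = 0.0301), so a fall of EGFR is not excluded. ERBB2 stood at 317 ± 6.95 CPM against 279 ± 31.8 (adjusted p = 0.265) and ERBB3 at 346 ± 3.36 CPM against 317 ± 24.8 (adjusted p = 0.344).

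All 22 mitotic genes fell (22 adjusted over the list alone), with a median of -2.03 (camera adjusted p = 5.55e-39, and adjusted p = 0.136 with an estimated correlation). CENPE fell from 121 ± 32.9 to 11.4 ± 4.93 CPM, KIF20A from 113 ± 14.4 to 15.3 ± 6.78 and CENPF from 179 ± 15.8 to 29.4 ± 12.3. DNA replication genes fell in 12 of 25 cases (22 adjusted over the list alone), median -0.76 (camera adjusted p = 2.12e-09, and adjusted p = 0.593 with an estimated correlation), among them PRIM1 (log2 fold change -1.16, SE 0.209, adjusted p = 0.00425). RRM2 (log2 fold change -1.33) and MCM10 (-1.48) were called at adjusted p = 0.0197 and 0.0483, and lost the call without MCF7L TamR replicate 1 (adjusted p = 0.0571 and 0.128) among other settings. ERK output genes gave 1 of 19 higher and 14 lower (1 and 16 adjusted over the list alone). Their median was -1.19 (camera adjusted p = 2.19e-18, and adjusted p = 0.136 with an estimated correlation). ETV4 fell from 63.2 ± 22.3 to 2.88 ± 0.377 CPM, SPRY4 from 165 ± 37.7 to 15.5 ± 1.12 and the ERK phosphatase gene DUSP6 from 112 ± 29.2 to 14.2 ± 1.24. ERBB receptors and ligands gave 1 of 12 higher and 4 lower (2 and 4 adjusted over the list alone). Their median was -0.19 (camera adjusted p = 0.000951, and adjusted p = 0.14 with an estimated correlation). Besides AREG the ligand genes BTC and HBEGF fell by 2.40 and 1.96 on the log2 scale.

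FOXO-responsive genes gave 6 of 20 higher and 0 lower (7 and 0 adjusted over the list alone). Their median was 0.41 (camera adjusted p = 9.16e-05, and adjusted p = 0.294 with an estimated correlation). PIK3IP1, which encodes an inhibitor of PI3K, rose from 6.80 ± 1.22 to 45.2 ± 8.05 CPM and TXNIP from 32.7 ± 15.2 to 109.6 ± 0.952. Interferon-stimulated genes gave 10 of 31 higher and 1 lower (13 and 1 adjusted over the list alone). Their median was 0.80 (camera adjusted p = 4.45e-05, and adjusted p = 0.618 with an estimated correlation). IFI6 rose from 6.11 ± 2.17 to 26.8 ± 1.75 CPM, HERC6 by 1.88 on the log2 scale and ISG15 from 11.7 ± 3.3 to 27.4 ± 2.15 CPM. Aryl hydrocarbon receptor targets gave 2 of 5 higher and 0 lower (3 and 0 adjusted over the list alone). Their median was 0.97 (camera adjusted p = 0.0107, and adjusted p = 0.294 with an estimated correlation). CYP1B1 rose from 56.9 ± 13.6 to 155 ± 21.3 CPM. Outside the lists, the chemokine gene CXCL8 fell from 84.7 ± 24.4 to 3.66 ± 1.04 CPM, the keratin gene KRT16 from 38.9 ± 8.78 to 1.84 ± 0.311, the transporter gene ABCC11 from 46.6 ± 20.7 to 2.04 ± 0.586 and SLPI from 19.0 ± 3.11 to 1.06 ± 0.359, while MYEOV and MAB21L3 fell by 6.42 and 4.88 on the log2 scale. The drug efflux pump gene ABCG2 rose from 0.863 ± 0.345 to 17.1 ± 3.95 CPM, the cholesterol transporter gene NPC1L1 from 1.12 ± 0.257 to 17.9 ± 4.43, and CUBN, RNF150 and VTCN1 by 4.03, 3.45 and 3.33 on the log2 scale. UGT2B17 (3.50) and TARP (5.56) share sequence with near copies and are uncertain. TFF1 fell by 1.43 (adjusted p = 0.0261), a call that ended in several settings, such as the fit without MCF7L TamR replicate 1 (adjusted p = 0.0861). ESR1, PGR, GREB1 and ERBB4 were not called (adjusted p = 0.118, 0.0724, 0.127 and 0.0875), though each passed in 1 or more of the settings run.

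In edgeR's test 1268 genes were higher and 1391 lower with sapitinib among 14753 tested (adjusted p under 0.05), 527 and 564 of them at least 2-fold. These counts depend on single libraries, as 808 and 811 genes were called without MCF7L TamR replicate 3, 753 and 889 without sapitinib replicate 1, 720 and 775 without replicate 2, and 657 and 708 without replicate 3. With all 18 libraries in the fit 2059 genes were higher. The share of changed genes that were higher was 47.7%, and 61.8% with library size alone as the scaling.

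In T47D TamR cells sapitinib lowered all tested mitotic and replication genes and most chaperone, ATF4 response and cholesterol genes, and raised most FOXO-responsive genes. Of 17 ERK output genes 9 fell and 2 rose. MKI67 (gene ID 4288), the Ki-67 proliferation marker, fell from 335 ± 14.5 to 13.6 ± 11.8 CPM (log2 fold change -4.60, SE 0.403, adjusted p = 2.82e-05, edgeR). BUB1 fell from 78.9 ± 3.26 to 2.99 ± 1.6 CPM (log2 fold change -4.70, SE 0.272, adjusted p = 1.69e-06) and MCM10 from 86.5 ± 3.28 to 2.95 ± 3.16 (log2 fold change -4.84, SE 0.457, adjusted p = 4.27e-05). PIK3IP1 rose from 24.1 ± 2.13 to 100.3 ± 9.76 CPM (log2 fold change 2.06, SE 0.0926, adjusted p = 2.96e-07). ERBB3 rose slightly (394 ± 26.1 CPM against 311 ± 11.5, log2 fold change 0.34, SE 0.0631, adjusted p = 0.00148), while EGFR and ERBB2 did not pass (adjusted p = 0.487 and 0.0938, the latter 0.0319 in DESeq2).

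All 22 mitotic genes (22 adjusted over the list alone) and all 25 replication genes (25 adjusted over the list alone) fell, with medians of -3.73 (camera adjusted p = 9.97e-32, and adjusted p = 0.161 with an estimated correlation) and -1.61 (camera adjusted p = 1.11e-30, and adjusted p = 0.157 with an estimated correlation). AURKB fell from 56.4 ± 2.91 to 2.49 ± 2.44 CPM, RRM2 from 138 ± 7.55 to 8.85 ± 9.95 and UHRF1 from 188 ± 4.9 to 12.7 ± 9.99. Of the 8 largest decreases, NEIL3, E2F7, SPC25, KIF15, NUF2, PIMREG and KIF4B act in DNA repair, the cell cycle or the spindle. Their log2 fold changes ran from -5.18 for NEIL3 to -5.00 for PIMREG, with KIF4B uncertain because of its near copy KIF4A. The other, the neuropeptide gene NMU, fell from 19.7 ± 1.74 to 0.561 ± 0.038 CPM. ERK output genes gave 2 of 17 higher and 9 lower (2 and 9 adjusted over the list alone). Their median was -1.63 (camera adjusted p = 0.00269, and adjusted p = 0.626 with an estimated correlation). DUSP4 fell by 3.45 on the log2 scale, EPHA2 and SPRED1 with log2 fold changes of -3.18 and -2.54. FOXO-responsive genes gave 13 of 19 higher and 0 lower (14 and 0 adjusted over the list alone). Their median was 0.41 (camera adjusted p = 2.52e-07, and adjusted p = 0.157 with an estimated correlation). KLHL24 rose from 51.2 ± 6.97 to 162 ± 10.2 CPM and CCNG2 from 43.3 ± 5.11 to 86.3 ± 11.6.

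Endoplasmic reticulum chaperone genes gave 1 of 17 higher and 12 lower (2 and 12 adjusted over the list alone). Their median was -0.50 (camera adjusted p = 3.65e-05, and adjusted p = 0.164 with an estimated correlation). HSPA5 fell from 481 ± 29.6 to 257 ± 5.3 CPM, PDIA3 from 241 ± 7.91 to 142 ± 5.07 and SDF2L1 from 49.5 ± 1.48 to 25.8 ± 2.08. ATF4 and amino acid response genes gave 1 of 21 higher and 14 lower (1 and 14 adjusted over the list alone). Their median was -0.35 (camera adjusted p = 0.000785, and adjusted p = 0.164 with an estimated correlation). SLC7A11, the cystine transporter gene, fell from 26 ± 1.43 to 5.40 ± 0.543 CPM and ASNS from 65.7 ± 2.49 to 36.4 ± 1.33, and CHAC1 fell by 1.40, a call that ended with all 18 libraries in the fit (adjusted p = 0.0596). Cholesterol synthesis and uptake genes gave 1 of 24 higher and 18 lower (1 and 18 adjusted over the list alone). Their median was -0.39 (camera adjusted p = 0.000785, and adjusted p = 0.626 with an estimated correlation). Aryl hydrocarbon receptor targets gave 3 of 4 higher and 0 lower (4 and 0 adjusted over the list alone) and missed the threshold in camera (adjusted p = 0.0578, 0.626 with an estimated correlation). The list passed with the replicate number as a block (adjusted p = 0.0438), without the filter on low counts (adjusted p = 0.0124) and without T47D sapitinib replicate 3 (adjusted p = 2.26e-06). CYP1A1 rose from 0.923 ± 0.333 to 10.3 ± 7.34 CPM and the receptor repressor gene AHRR from 6.88 ± 0.232 to 27.1 ± 7.51. TIPARP rose by 0.46 on the log2 scale (adjusted p = 0.0451), a call that ended in several settings, such as the fit without T47D TamR replicate 1 (adjusted p = 0.0962). HMGCS2, the ketone body enzyme gene, had 2 counts before sapitinib and 10.4 ± 6.33 CPM with it (ratio 168, counting interval 46.1 to 1390). RHBDL3, AHNAK2, MYO7A and PLA2G4C rose by 2.64 to 3.35 on the log2 scale. The muscarinic receptor gene CHRM1 rose from 0.698 ± 0.0966 to 11.4 ± 4.06 CPM, and the cholesterol exporter gene ABCA1 rose from 12 ± 2.7 to 76.7 ± 12.9 CPM. ERBB4 rose but stayed low, at 0.927 ± 0.312 CPM against 0.305 ± 0.224 (adjusted p = 0.0351, and 0.124 with all 18 libraries in the fit). ESR1, PGR, GREB1 and TFF1 did not pass (adjusted p = 0.409, 0.687, 0.718 and 0.398). In edgeR's test 3410 genes were higher and 3417 lower among 15372 tested (adjusted p under 0.05), 818 and 930 of them at least 2-fold.

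**Figure D3:**
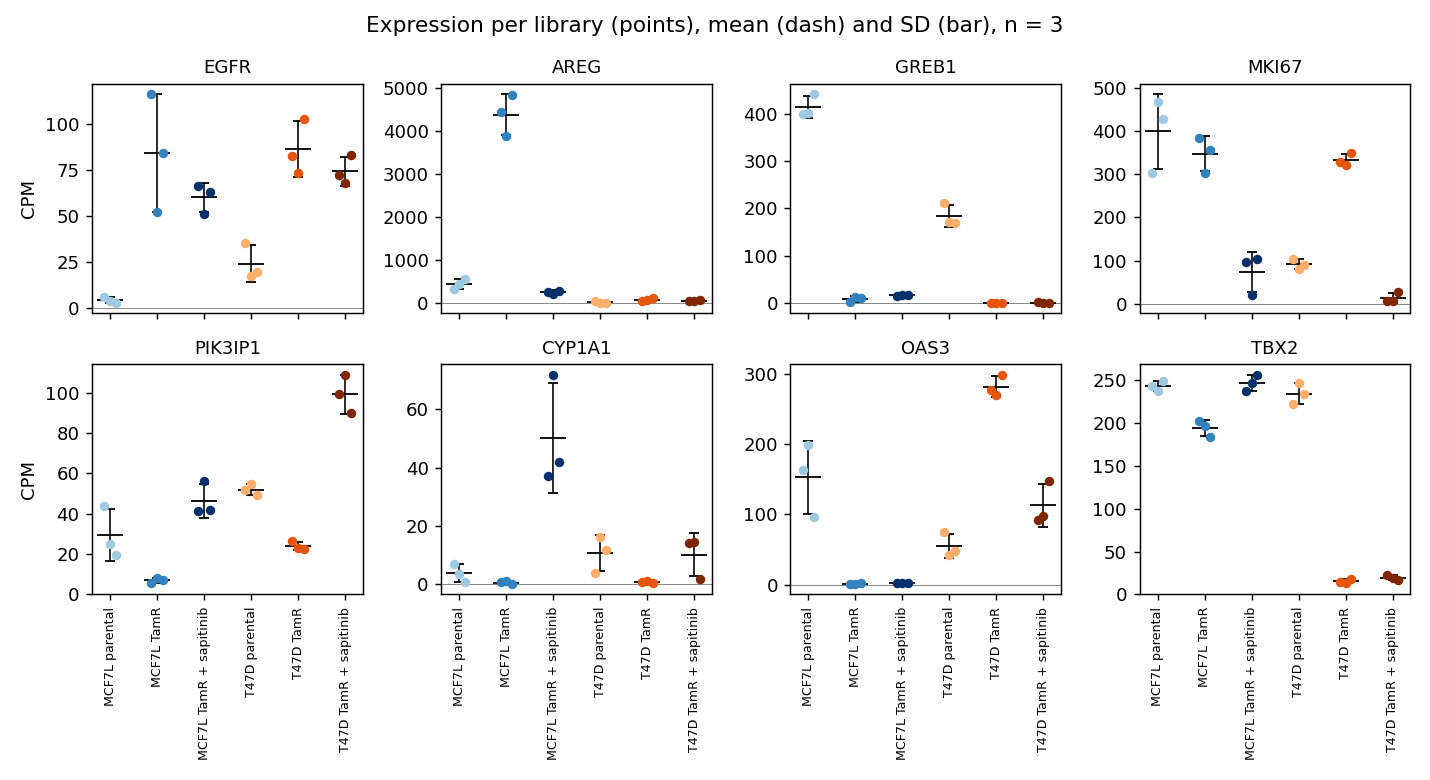
CPM of 8 genes in the 18 libraries, scaled over all 18 libraries, with points for libraries, a dash for the mean and a bar for 1 SD (n = 3 per group, groups named as labelled). AREG is highest in MCF7L TamR, MKI67 falls with sapitinib in both lines, and TBX2 is alike in both parental groups and low in T47D TamR.

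The 2 lines shared more changes with sapitinib than independent calls would, though not most of those called in T47D. They differed in the depth of the mitotic fall and in other genes. Among the genes tested in both lines, 2541 were called in MCF7L and 6431 in T47D. Of 14256 genes tested in both, 836 fell in both, where independent lists would share 303.46, and 515 rose in both, against 270.05, while 175 went opposite ways, against 572.75. Across genes, which are not independent replicates, the fold changes correlated at r = 0.404. With a library left out the 836 became 453 to 967 and the 515 became 251 to 789, and with a log2 fold change of at least 1 in both lines they were 281 and 94. The genes that fell furthest in both were PIF1, CENPE, KIF14 and DEPDC1 (log2 fold changes -3.63, -3.41, -3.38 and -3.18 in MCF7L, -4.48, -4.12, -4.75 and -4.08 in T47D). CYP1A1, PIK3IP1, GPNMB and SRMS rose furthest in both, GPNMB from 2.91 ± 0.594 to 17.6 ± 6.51 CPM in MCF7L and from 50.2 ± 20.8 to 217 ± 58.2 in T47D, SRMS by 1.45 and 1.46 on the log2 scale.

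In the test of the difference, 14 of 22 mitotic genes fell further in T47D (20 adjusted over the list alone), median difference -1.51 (camera adjusted p = 1.8e-10, and adjusted p = 0.520 with an estimated correlation). Replication genes did so in 15 of 25 cases (20 adjusted over the list alone), median -0.90 (camera adjusted p = 1.81e-10, and adjusted p = 0.520 with an estimated correlation). Interferon-stimulated genes were lower in the difference in 12 of 32 cases and higher in 1 (16 and 1 adjusted over the list alone), median -1.07 (camera adjusted p = 3.23e-08, and adjusted p = 0.520 with an estimated correlation). ERK output genes gave 2 of 19 higher and 5 lower (2 and 6 adjusted over the list alone). They had a median of 0.02, a camera direction of down and an adjusted p = 0.877 (0.957 with an estimated correlation). The fall of CXCL8 in MCF7L was not matched in T47D (difference 5.12, SE 1.04, adjusted p = 0.00375, edgeR), and the call ended without T47D sapitinib replicate 3 (adjusted p = 0.109). Its counts in T47D were too low for the test within that line. The antimicrobial peptide gene DEFB1 (7.84, adjusted p = 0.00274), AMIGO2 (5.81) and SAMD9 (5.40) were the other most positive differences. ANKRD2 (-7.00, adjusted p = 0.00329), C1QTNF2 (-5.28) and KCNC1 (-4.93) were among the most negative, and TARP (-8.58) lost its call in most settings and is uncertain as a paralog. None of EGFR, ERBB2, ERBB3, ERBB4, ESR1, PGR, GREB1 and TFF1 passed, with adjusted p from 0.0627 for TFF1, which passed in DESeq2 (adjusted p = 0.0077), to 0.795 for ERBB4. In all, 912 genes were higher and 1401 lower in the difference among 15961 tested (edgeR), with 538 higher and 903 lower without T47D sapitinib replicate 1, 583 higher without T47D sapitinib replicate 2 and 916 lower without MCF7L sapitinib replicate 3.

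**Figure D4:**
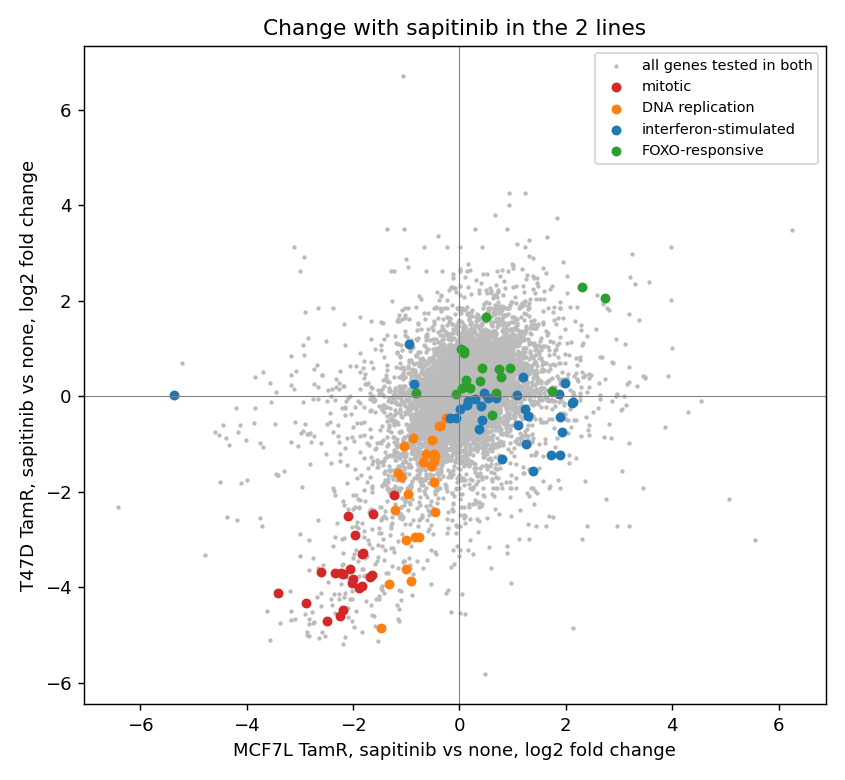
Log2 fold change with sapitinib in T47D TamR (vertical) against MCF7L TamR (horizontal) for 14256 genes tested in both lines, grey, with 4 of the fixed lists in colour. The 22 mitotic genes lie at medians of -2.03 in MCF7L and -3.73 in T47D.

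How far sapitinib moved TamR cells back toward the parental level was asked by counting genes called in both contrasts of a line. In MCF7L 1149 of 1488 such genes moved in opposite directions (77.2%), 544 of them up in TamR and down with sapitinib and 605 the reverse, while 339 moved the same way. AREG, SPRY4, BTC and CHAC1 were among those that rose in TamR and fell with sapitinib, and PIK3IP1, TXNIP, GATA3 and TAP1 among those that fell and rose (TAP1 from 61.3 ± 14.6 CPM in parental to 6.52 ± 1.09 in TamR and 26.4 ± 2.88 with sapitinib). With a library left out the opposite genes numbered 609 to 1527 and the same-direction genes 172 to 366, and 420 and 108 had a log2 fold change of at least 1 in both contrasts. Independent calls would give 587.69 opposite and 589.42 same. In T47D 3758 of 5241 genes moved in opposite directions (71.7%) and 1483 the same way, against 2548.2 and 2548.1 for independent calls, where the first contrast uses the libraries labelled T47D parental. With a log2 fold change of at least 1 in both contrasts they were 933 and 237. Both contrasts of a line use the TamR libraries, which alone gives a negative relation. The covariance of the fold changes was -0.282 in MCF7L against -0.0331 in 20 simulations of unchanged groups, and -0.4 against -0.0222 in T47D, a difference of -0.249 and -0.378. The correlation was -0.248 and -0.24 against -0.5 and -0.502 in the simulations. Simulated unchanged groups gave on average 0 and 0.05 opposite calls, since hardly any gene is called where none changes. These numbers therefore do not show how many opposite calls the shared libraries add among changed genes. Part of the excess over independent calls may come from the shared libraries, of which there are 3, too few to split.

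The authors' deposited table for each comparison lists genes with an adjusted p of at most 0.0498 and an absolute log2 fold change of at least 0.58. The lowest base mean of a listed gene ran from 67.9 to 98, so the numbers listed are not at the thresholds used here. The tables describe the same libraries, so a match in direction was all but fixed in advance and is no separate evidence. For MCF7L TamR the authors' deposited table held 1463 higher and 1564 lower genes, and all 2901 that matched a tested gene had the same direction here. The authors' deposited table for T47D TamR held 2265 higher and 2609 lower genes, with the same direction here for all 4662 matched. For sapitinib the authors' deposited tables held 751 higher and 750 lower genes in MCF7L and 1057 and 1079 in T47D, with the same direction here for all 1437 and 2045 matched. Of the genes matched, 2884, 4652, 1283 and 2002 were also called here, in the order in which the authors' deposited tables are named.

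Over the 23 tested lists, camera with the preset correlation of 0.01 called 5 in MCF7L TamR against parental and 5 in T47D TamR against the libraries labelled T47D parental. It called 16 and 9 with sapitinib in MCF7L and T47D, and 9 and 7 in the differences between lines for TamR and for sapitinib. With the correlation estimated from the data it called 0 in each, with 2, 1, 4, 5, 1 and 1 lists at an unadjusted p under 0.05. The 5 lists of MCF7L TamR became 10 without the filter on low counts and 4 to 10 with a library left out, and the 9 of the TamR difference 5 to 9.

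**Figure D5:**
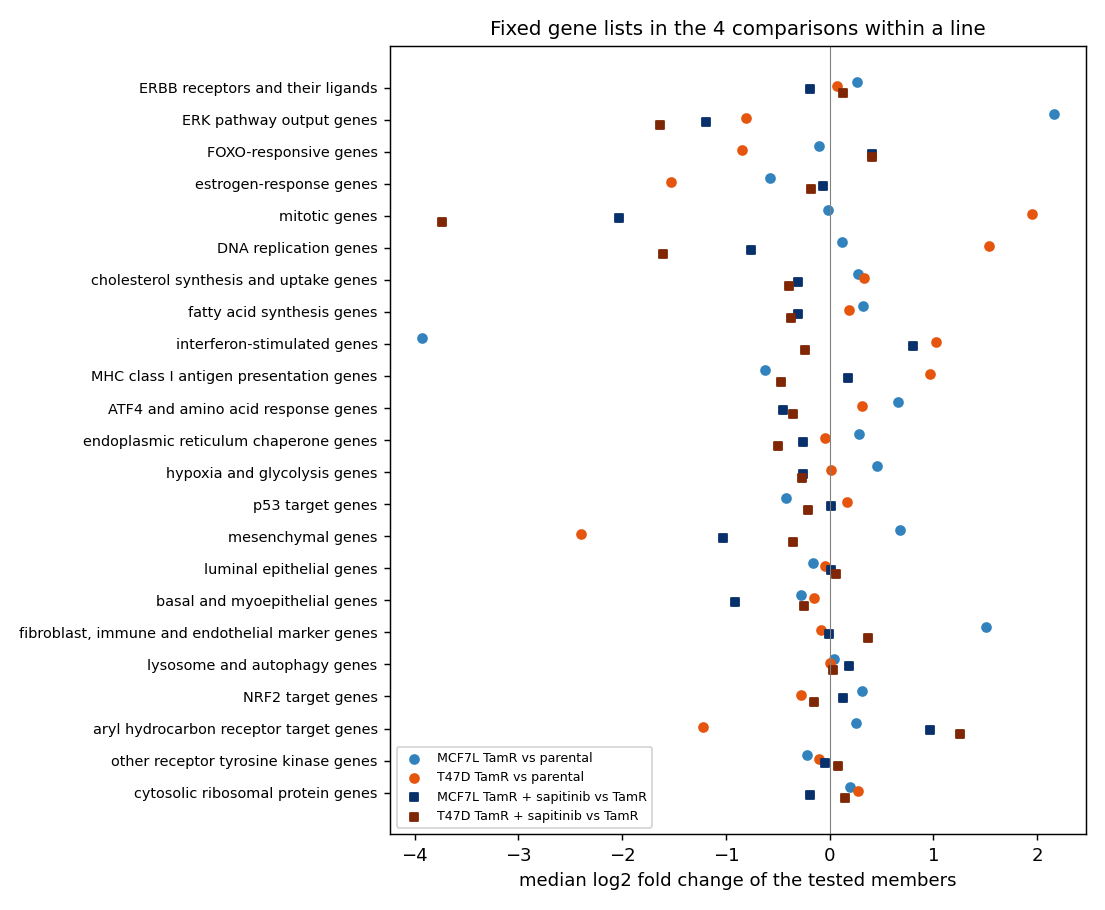
Median log2 fold change of the tested members of 23 fixed gene lists, one point per comparison within a line. Mitotic genes lie at -2.03 and -3.73 with sapitinib, and interferon-stimulated genes at -3.93 in MCF7L TamR against parental and 1.02 in T47D TamR against the libraries labelled T47D parental.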

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

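Of the tests in this part, the splits of the libraries, the label and window tests of the first pattern, the test of medium and drug in the second, the test of starting level in the third and the tests of a single library in both were chosen after the results were seen. The genes, called lists and gene counts of the next 3 paragraphs were picked out because the 2 lines differ in the same contrast by a direct test of that difference (edgeR, adjusted p under 0.05, or camera with the preset correlation for lists). With an estimated correlation camera called none of these lists. Values are T47D minus MCF7L differences of log2 fold changes. Where a gene had no count in a group, the size of its difference depends on the prior count, and the sign and the call are what the test gives.

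For TamR against parental, 4556 genes were higher and 4714 lower in the difference, and the T47D side uses the libraries labelled T47D parental. Of the ERBB list, BTC -8.43 and EGFR -2.56 were lower and EPGN 3.76 higher, and of the ERK output list SPRY4 -8.015 and ETV5 -6.82 were lower and EPHA4 4.77 higher. The estrogen-response list went both ways (12 higher and 13 lower of 34, median 0.01), with PGR -4.88, TFF1 -4.04 and GREB1 -2.09 on one side and SUSD3 3.98 and CA12 3.805 on the other. So did the ATF4 response list (4 higher and 5 lower of 21, median -0.19), with SLC7A11 -2.995 and CHAC1 -2.48 against ALDH1L2 3.83. The named mesenchymal genes (VIM -10.50, FN1 -4.76, LOX -4.19 and SERPINE1 -3.16) and FOXO-responsive genes (SESN3 -8.975, IRS2 -5.435 and IGF1R -1.76) were lower in the difference. So were the transcription and growth factor genes SOX2 -12.76, MAF -12.59, MEF2C -9.03, BMP2 -10.04, AFF3 -6.18 and MEIS2 -2.255, together with GALNT5 -15.11, VWDE -12.04, STOX2 -12.01, DENND1B -11.52 and PABPC1L2B -10.85, and PCED1B -9.52, ARHGAP20 -8.85, GNG11 -8.67, FLG -8.62 and ZC3HAV1L -7.70.

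Higher in the difference were interferon-stimulated genes (OAS2 9.25, OAS3 9.07, XAF1 8.69, IFI44 7.965 and MX1 3.39) and antigen presentation genes (PSMB9 9.33, PSMB8 4.62, TAP1 4.17, TAPBP 3.26, TAP2 2.95 and HLA-B 2.05). Mitotic and replication genes (POLE2 4.28, BUB1 3.04, MCM10 3.01, BUB1B 2.67, CENPA 2.26 and UHRF1 2.06) were higher as well. Of the luminal list 7 of 20 were higher and 4 lower (median 0.08), with MUC1 5.225, ELF3 2.76, GATA3 2.305 and KRT18 1.91 higher and ESR1 -2.41 lower. Outside the lists, SSX5 14.07, TEX11 10.64, PRAME 9.85 and CTAG1B 8.645, MDFI 13.56, FAM133A 13.13, P2RX7 12.75, FSTL5 10.61 and ABCA4 10.40, and CHGA 6.47, RAMP1 5.94 and VSTM2L 5.54 were also higher. List medians were 5.05 for interferon-stimulated, 2.05 for MHC class I, 1.98 for mitotic, 1.39 for replication and -2.36 for ERK output genes.

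For sapitinib, 912 genes were higher and 1401 lower in the difference. Of the named genes that fell in T47D, these fell further there than in MCF7L (E2F7 -3.61, MCM10 -3.38, NEIL3 -3.00, UHRF1 -2.97, SPC25 -2.90, RRM2 -2.62 and KIF15 -2.51, and KIF4B -2.44, MKI67 -2.37, AURKB -2.30, BUB1 -2.22, NUF2 -2.19 and PIMREG -2.145). Of the ERK output list, DUSP4 -2.66, EPHA2 -1.91 and SPRED1 -1.44 were lower and ETV4 3.84 higher in the difference, as were the EGFR ligand genes BTC 2.53 and AREG 3.52. Of the interferon-stimulated genes, HERC6, IFI6 and ISG15 rose in MCF7L and did not pass in T47D (HERC6 -2.32, IFI6 -2.27 and ISG15 -1.52). Lower in the difference were further TARP -8.585, ANKRD2 -7.00, C1QTNF2 -5.28 and KCNC1 -4.93, and ABCG2 -4.63, VTCN1 -3.12, TXNIP -1.66 and SDF2L1 -0.83. Genes that fell in MCF7L were higher in it (CXCL8 5.12, MYEOV 4.10, KRT16 3.51, SLPI 3.40 and ABCC11 2.715), as were DEFB1 7.84, AMIGO2 5.815 and SAMD9 5.40 and the genes that rose in T47D, RHBDL3 3.73, MYO7A 3.66, ABCA1 3.46, CHRM1 3.065, PLA2G4C 2.43, AHNAK2 2.11 and CCNG2 0.95. List medians were -1.51 for mitotic, -0.90 for replication and -1.07 for interferon-stimulated genes.

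The calls were compared with other splits of the same libraries. Within a line there are 10 splits, too few to reach 1 in 20, and the labelled split alone gave called genes: 1 of 10 splits in each comparison was as large, with 0 called genes in the others. The others mix libraries of both groups, which widens the spread in the fit and by itself lowers the number of calls. At an unadjusted p under 0.05 the others gave up to 1043 (MCF7L TamR), 420 (T47D TamR), 1513 (MCF7L sapitinib) and 507 (T47D sapitinib). For the differences between lines 1 of 100 splits reached the 9270 genes of TamR, the labelled one, with 7016 in the highest other. For sapitinib 3 of 100, the labelled one included, reached its 2313 genes, with 3742 in the highest other. The 2 others kept the T47D libraries as labelled and mixed only those of MCF7L, so they still hold the T47D effect. Numbers of called lists are another matter: 7 of 10 splits called as many lists as the 5 of MCF7L TamR (highest 14), 9 of 10 as many as the 5 of T47D TamR (highest other 8). For sapitinib 1 of 10 called as many as the 16 of MCF7L sapitinib (highest other 12) and 5 of 10 as many as the 9 of T47D sapitinib (highest other 11). In the differences between lines 33 of 100 splits called as many as 9 lists (highest 12) and 67 of 100 as many as 7 (highest 15). Outside sapitinib in MCF7L, regroupings of the libraries thus reach the number of lists called with the preset correlation. Every other split within a line mixes both groups unevenly, so part of the labelled contrast remains. In the differences between lines, 5 of the other splits reaching 9 lists and 18 of those reaching 7 kept 1 line as labelled. The splits are thus not groupings without a difference and do not show what chance alone would call. The number of lists is no evidence by itself.

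The first pattern weighed, which came from the distances between groups and from the windows, is that T47D TamR libraries lie farther from the libraries labelled T47D parental than MCF7L parental does. A swap of the TamR labels between lines was tested with 54 genes that separate the parental groups by a log2 difference of at least 5: in T47D TamR 83.3% and in MCF7L TamR 81.5% of them lay nearer their own parental group as labelled. This speaks against a swap only if the libraries labelled T47D parental are T47D cells. In these genes T47D TamR lay on the side of those libraries, unlike in the regional profile. An origin of the libraries labelled T47D parental from MCF-7-type cells predicts that their regional profile lies nearer MCF7L, and it did, with a root mean square window difference of 0.167 from MCF7L parental (0.172 to 0.18 for its single libraries) against 0.388 from T47D TamR. The windows also raised this question, so these values restate the observation and are no separate test of it. MTAP and TFAP2B stood above MCF7L parental in those libraries (13.6 ± 4.45 against 6.54 ± 0.0717 CPM and 4.67 ± 1.74 against 0.427 ± 0.0402) and far below T47D TamR, and no test here explains these levels. A regional change during selection of the TamR cells also predicts a low slope of parental on TamR window differences. The slope was 0.0301, and 0.0809 without the window that differs most. Both explanations predict a low slope, so it cannot decide between them. A change in the TamR cells alone would not account for the likeness of both parental groups. Their window difference of 0.167 was below the 0.241 of MCF7L TamR from its own parental group. These are the same windows that raised the question, so this likeness is no separate test against selection. The libraries labelled T47D parental may thus not be T47D cells, and no test here settles it. Results for T47D TamR against those libraries and for the TamR difference between lines would then compare unlike cells. The sapitinib contrasts do not compare against them and share only the filter, scaling and spread of the fit with them.

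The second pattern is the loss of interferon-stimulated genes in MCF7L TamR, with a median of -3.93. Library sizes alone in place of TMM gave -3.989, and the value nearest 0 without any one library was -3.618 (without MCF7L TamR replicate 1), so neither scaling nor a single library accounts for it. An effect of medium and drug alike in both lines predicts lower values in T47D too, where the median was 1.021. That test relies on the libraries labelled T47D parental, so the explanation remains open.

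The third pattern is the deeper fall of mitotic genes with sapitinib in T47D TamR, with a median difference of -1.51. It was -1.547 with library sizes alone and -1.3 at the value nearest 0 with a library left out (MCF7L TamR sapitinib replicate 1), which speaks against scaling and against a single library. Single libraries still overlapped between the lines. With sapitinib MKI67 stood at 97.13, 21.51 and 102.6 CPM in MCF7L and 6.585, 6.881 and 26.91 in T47D, scaled over all 18 libraries. A higher starting level predicts an opposite difference of the same size between the TamR lines before sapitinib. That difference was 0.138 (quartiles -0.0227 to 0.313), and -1.28 with sapitinib, so the starting level does not account for it. The dose and duration may differ between lines, which the labels leave open and these values (0.138 and -1.28) do not test.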

How the results depend on the processing

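Leaving out libraries for overlaps, opposite changes, single gene lists and numbers of lists was chosen after the data were seen, and all other settings were fixed before. Counts of changed genes stayed within 1.5 times in T47D and in MCF7L TamR against parental. For sapitinib in MCF7L the 1268 higher genes became 2059 with all 18 libraries fitted, where the spread is shared with T47D, and 657 to 1726 with a library left out, the 1391 lower genes 708 to 1551. The difference in sapitinib change gave 538 to 1196 higher and 903 to 1540 lower genes with a library left out. The cause was not tested.

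With a log2 fold change of at least 1 in both contrasts, 288 higher and 732 lower genes were shared for TamR and 94 and 281 for sapitinib, and 420 opposite and 108 same-direction genes remained in MCF7L and 933 and 237 in T47D, fewer by construction. With a library left out, genes shared for sapitinib were 251 to 789 higher and 453 to 967 lower, and in MCF7L 609 to 1527 opposite and 172 to 366 same-direction.

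Lists called in MCF7L TamR were 10 without the filter on low counts and 4 to 10 with a library left out, and 5 to 9 in the TamR difference between lines, and the cause was not tested. With an estimated correlation camera called 0 lists in every comparison; the cause was not tested further.

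Results that changed direction were never called, and each did so with a library left out. They were small in the main fit apart from ERBB4 in the sapitinib difference, at -0.6072. For the ERK list in the sapitinib difference the direction is that of camera, which was down and turned up in 4 such fits, at medians of 0.1104, 0.09978, 0.03708 and 0.01259. Its median, 0.02 in the report, ran from -0.04483 to 0.1104 with a library left out and was -0.01998 with library sizes alone. The log2 values that changed sign were those of GREB1 with sapitinib in T47D from -0.3645 to 0.6551, ERBB2 in the TamR difference from -0.06231 to 0.1168, and in the sapitinib difference EGFR from -0.03412 to 0.5619, ERBB2 from -0.1706 to 0.006179, ERBB4 from -1.331 to 0.07766 and ESR1 from -0.1476 to 0.05726. Of called named genes, 51 of 51 in MCF7L TamR and 57 of 57 in T47D TamR kept the call under every alternative. With sapitinib 36 of 39 in MCF7L and 41 of 44 in T47D kept it. In the differences between lines only 16 named genes each were run under the alternatives. Of those called, 12 of 13 for TamR and 6 of 8 for sapitinib kept the call. No called gene among those run reversed. The differences of the other genes listed among the flagged results were not tested for stability.

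The replicate numbers are shared by all groups without a stated pairing. Same-numbered libraries correlated above 0.1 in 0 of 3 pairs for TamR in either line and in 2 of 3 for sapitinib in each, and 0, 0, 6 and 4 of the 6 libraries of a comparison correlated best with their own number (MCF7L TamR, T47D TamR, MCF7L and T47D sapitinib). With the number as a replicate block 1080 genes were higher and 1138 lower with sapitinib in MCF7L, and 704 and 1202 in the sapitinib difference. The block moved no count of calls by more than 1.5 times and changed no called list, but brought the aryl hydrocarbon receptor list in T47D under the threshold and the lists called with sapitinib in T47D from 9 to 12.

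The simulations changed 200 genes at this depth and this spread between replicates, which were not separated. Of simulated changes of 1.5 times, 14.9% to 62.7% were recovered across the 6 comparisons. The simulations called 106 to 162 genes in a comparison, against 2313 to 11475 in the data. The adjusted threshold is stricter where fewer genes change, so these shares do not give the recovery in the data.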

Other observations

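No further test was chosen after the results were seen in this part, which gives the other lists that camera called and 3 that it did not call within a line. Lists not named for a comparison here or in the report were not called in it. With sapitinib in MCF7L TamR, camera called further lists of metabolism, stress response and cell type. Fatty acid synthesis genes gave 0 higher and 3 lower of 11 (0 and 3 adjusted over the list alone; median -0.30, adjusted p = 0.0241, 0.618 with an estimated correlation). ATF4 response genes gave 1 higher and 7 lower of 20 (2 and 9 adjusted over the list alone; median -0.45, adjusted p = 0.00498, 0.618 with an estimated correlation). Hypoxia and glycolysis genes gave 0 higher and 7 lower of 21 (0 and 7 adjusted over the list alone; median -0.25, adjusted p = 0.0191, 0.62 with an estimated correlation). Chaperone genes gave 0 higher and 2 lower of 17 (0 and 2 adjusted over the list alone; median -0.26, adjusted p = 0.0184, 0.618 with an estimated correlation). Basal genes gave 1 higher and 6 lower of 14 (2 and 7 adjusted over the list alone; median -0.92, adjusted p = 0.000951, 0.136 with an estimated correlation). Ribosomal protein genes gave 0 higher and 2 lower of 74 (0 and 0 adjusted over the list alone; median -0.19, adjusted p = 0.00262, 0.618 with an estimated correlation). Lysosome genes gave 3 higher and 0 lower of 24 (3 and 0 adjusted over the list alone; median 0.18, adjusted p = 0.00574, 0.618 with an estimated correlation). NRF2 targets gave 5 higher and 1 lower of 18 (6 and 1 adjusted over the list alone; median 0.13, adjusted p = 0.0235, 0.618 with an estimated correlation). MHC class I genes gave 2 higher and 0 lower of 12 (2 and 0 adjusted over the list alone; median 0.18, adjusted p = 0.0206, 0.618 with an estimated correlation).

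With sapitinib in T47D TamR, estrogen-response genes gave 3 higher and 10 lower of 34 (3 and 10 adjusted over the list alone; median -0.18, adjusted p = 0.0476, 0.626 with an estimated correlation). Ribosomal protein genes gave 16 higher and 1 lower of 74 (12 and 1 adjusted over the list alone; median 0.15, adjusted p = 0.0459, 0.732 with an estimated correlation). In the sapitinib difference between lines, MHC class I genes gave 0 higher and 5 lower of 13 (0 and 8 adjusted over the list alone; median -0.78, adjusted p = 4.78e-05, 0.520 with an estimated correlation). NRF2 targets gave 0 higher and 8 lower of 18 (1 and 9 adjusted over the list alone; median -0.33, adjusted p = 0.000532, 0.520 with an estimated correlation). Estrogen-response genes gave 3 higher and 12 lower of 34 (5 and 13 adjusted over the list alone; median -0.32, adjusted p = 0.00260, 0.567 with an estimated correlation). Ribosomal protein genes gave 5 higher and 0 lower of 74 (0 and 0 adjusted over the list alone; median 0.34, adjusted p = 1.74e-07, 0.598 with an estimated correlation). In the TamR difference, which uses the libraries labelled T47D parental, FOXO-responsive genes gave 4 higher and 10 lower of 20 (4 and 10 adjusted over the list alone; median -0.69, adjusted p = 0.0288, 0.738 with an estimated correlation). Hypoxia genes gave 1 higher and 11 lower of 21 (1 and 11 adjusted over the list alone; median -0.53, adjusted p = 0.0288, 0.755 with an estimated correlation). Mesenchymal genes gave 1 higher and 6 lower of 11 (1 and 6 adjusted over the list alone; median -3.16, adjusted p = 0.0288, 0.683 with an estimated correlation). NRF2 targets gave 2 higher and 12 lower of 18 (2 and 12 adjusted over the list alone; median -0.62, adjusted p = 0.0288, 0.738 with an estimated correlation).

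Beside the luminal and mesenchymal lists, camera called p53 targets, other receptor tyrosine kinases and markers of fibroblast, immune and endothelial cells in no comparison within a line. In MCF7L TamR these 3 gave 1 higher and 10 lower of 22 (1 and 10 adjusted over the list alone; median -0.42, adjusted p = 0.309, 0.862 with an estimated correlation), 2 higher and 5 lower of 13 (3 and 5 adjusted over the list alone; median -0.22, adjusted p = 0.475, 0.862 with an estimated correlation) and 3 higher and 1 lower of 4 (3 and 1 adjusted over the list alone; median 1.51, adjusted p = 0.577, 0.886 with an estimated correlation). The 13 mitochondrially encoded genes are absent from the count table, so that list has no result. The window that differs most between the TamR lines, at -2.83, holds a protocadherin cluster, a family of near-identical neighbours, and stood at 1.16 between the parental groups as labelled.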
